A study of Mus musculus with 14 samples.

How the data were processed

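RNA sequencing measured gene expression in mouse CD4+ T cells carrying a YFP reporter of the cytokine interferon-gamma on the C57BL/6 background. Per the labels, cells were taken from spleen and peripheral lymph nodes. Naive cells (CD4+ CD44- CD62L+) were sorted directly. The other cells were enriched CD4+ T cells, not sorted naive cells, held for 4 days under conditions that favour the Th1 fate: plate-bound anti-CD3 and anti-CD28 at 1 µg/ml, IL-2 and IL-12 at 10 ng/ml and anti-IL4 at 10 µg/ml. SGC0946, an inhibitor of the histone methyltransferase DOT1L, or SGC0649, its inactive control compound, was present at 1 µM, and reporter-positive (YFPpos) and reporter-negative (YFPneg) cells were sorted afterwards. An untreated or vehicle-treated Th1 culture was not analysed here.

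The authors deposited a table of raw read counts per gene for 14 libraries, made with featureCounts on genome build GRCm38, together with a summary of read counts in each assignment category. The values are whole-number counts without normalization. The file name and a biotype column give reverse-strand counting and protein-coding rows. The labels name edgeR, limma and featureCounts without versions, and the aligner and annotation release are not given in the sources used here. The table held 22048 genes with distinct Ensembl IDs, of which 21858 (99.14%) were found in GENCODE release M21 (GRCm38), all on the same chromosome. The table used 103 gene names for more than 1 ID, and tests were run per ID.

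The libraries formed 5 groups: naive (n = 3), YFPneg with SGC0649 (n = 2), YFPpos with SGC0649 (n = 3), YFPneg with SGC0946 (n = 3) and YFPpos with SGC0946 (n = 3). Sample titles carry the numbers 61 to 63 for SGC0649 and 91 to 93 for SGC0946 in both sorts, and YFPneg cells of number 63 were not analysed here. Whether both sorts of a number came from 1 culture is not given in the sources used here. Replicates are written 1 to 3 in that order. The study design calls them biological replicates, and nothing else in the sources used here says that they came from separate animals. The numbers were checked for pairing, and the fit reported first has no block. Total counts ranged from 14486577 to 31614057 per library. Counting intervals and floors given below cover counting error only, and reads amplified by PCR are not independent molecules. Intervals of log2 fold changes come from the model and include the spread between libraries. Intervals of a share of increases are binomial over genes, which are not independent replicates.

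Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 12343 genes. Libraries were scaled with TMM factors, and all 14 libraries entered one quasi-likelihood negative binomial model with a coefficient for each group. The groups therefore shared 1 estimate of spread, with a common dispersion of 0.00831, a biological coefficient of variation of 9.12% and 7.63 prior degrees of freedom. The 7 comparisons were tested with edgeR's quasi-likelihood F test and adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. The seventh comparison was the interaction, meaning the SGC0946 effect in YFPpos cells minus that in YFPneg cells. Log2 fold changes carry edgeR's default prior count of 0.125. Standard errors were derived as the absolute log2 fold change divided by the square root of F, and intervals are 95% intervals. Group levels are TMM-scaled counts per 1000000 (CPM) with their SD. Where every library of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where the group total was 1 to 3 counts, the ratio is given with its 95% counting interval.

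The named genes followed a rule. Part 1 took a fixed set of genes in each comparison, of which Ifng, Tbx21, Dot1l, Gata3 and Foxp3 are described. Some genes that the rule names are not reported here. Part 2 took the 6 higher and 6 lower genes with the largest absolute log2 fold change past the threshold, a mean log2 CPM of at least 3 and no overlap between the libraries of the groups compared, a condition not applied to the interaction. Part 3 took up to 4 members with the smallest p of each gene list described. Members named as exceptions to the direction of their list, and the genes named in the paragraphs on gene families at the end, fall outside this rule and were chosen after their values were seen. The rule, the 25 gene lists, the groups, the tests and 9 alternatives per comparison were fixed before the data were examined.

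Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01 between genes, camera with the correlation estimated from the data, and fry, each adjusted over the lists of a comparison. Where a camera adjusted p stands below without further words, it is that with the preset correlation. A list member is said to have risen or fallen when it passed the gene test over all genes. A second count, adjusted over the list alone, is given where it differs for the direction named, and where a single count stands, both were equal. Counts said to be adjusted over all genes are given without the second count.

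The test was tried on counts simulated from the means, dispersions and library sizes of these data, with known changes added to genes of at least 10 CPM. In the YFPpos comparison of the compounds it recovered 91.0% of 67 genes changed 1.5-fold and all 67 changed 2-fold, and 5.37% of calls were false. In the YFPneg comparison it recovered 77.6% and 97.0% of 67 genes at these folds, with 4.19% of calls false. The simulation gave each gene the same spread in all groups and changed no gene under 10 CPM. These rates therefore do not cover a spread that differs between groups, or changes in weaker genes.

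The alternatives were DESeq2 size factors, no filter on low counts, a robust fit, a replicate block, counts thinned to the smallest library total, a fit to the compared groups alone, the Wald test of DESeq2 1.42.0, limma-voom and each library left out in turn. A block by the numbers in the titles was tried for YFPpos against YFPneg cells. An alternative without YFPneg SGC0946 replicate 3 and YFPpos SGC0946 replicate 2, which stood apart from their groups, was chosen after seeing the data. Shared sequence was counted as 75-base stretches of a transcript that also occur in another annotated transcript. A genome sequence was not used. Checks and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.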

Results

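The data were read counts from 14 RNA sequencing libraries of mouse CD4+ T cells. They covered sorted naive cells (n = 3) and cells sorted by an interferon-gamma reporter after 4 days of Th1 polarization with the DOT1L inhibitor SGC0946 or the inactive control compound SGC0649. The cultured groups were YFPneg SGC0649 (n = 2), YFPpos SGC0649 (n = 3), YFPneg SGC0946 (n = 3) and YFPpos SGC0946 (n = 3). Mean total counts, in M for units of 1000000 counts, were 17.5 M ± 0.752 (SD, n = 3) in naive cells and 19.4 M ± 0.339 (SD, n = 2) in YFPneg SGC0649 cells. They were 16.4 M ± 2.13 (SD, n = 3) in YFPneg SGC0946 cells, 22.2 M ± 1.28 (SD, n = 3) in YFPpos SGC0649 cells and 26.0 M ± 5.06 (SD, n = 3) in YFPpos SGC0946 cells.

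Mitochondrially encoded genes took 1.37% to 1.80% of counts and the 10 largest genes 4.05% to 4.83%. Between 57.2% and 65.2% of reads were assigned to genes. A pair of libraries stood apart from their groups. YFPneg SGC0946 replicate 3 had the smallest total, 14.5 M. In YFPpos SGC0946 replicate 2, 3.61% of reads were unmapped, against 6.44% to 8.35% in the other YFPpos libraries and 3.14% to 4.62% in YFPneg libraries.

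The reporter sort can be read from Ifng itself, which encodes interferon-gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892, GRCm38). Its level was 737 CPM ± 169 (SD, n = 3) in YFPpos SGC0649 cells, 33.8 ± 11.8 (n = 2) in YFPneg SGC0649 cells and 0.0623 ± 0.108 (n = 3) in naive cells. With SGC0946 it was 645 CPM ± 97.3 (SD, n = 3) in YFPpos and 66.8 ± 42.5 (n = 3) in YFPneg cells. Tbx21, the gene of the Th1 master regulator T-bet (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), stood at 265 to 322 CPM in all 4 cultured groups and at 0.477 in naive cells.

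**Figure D1:**
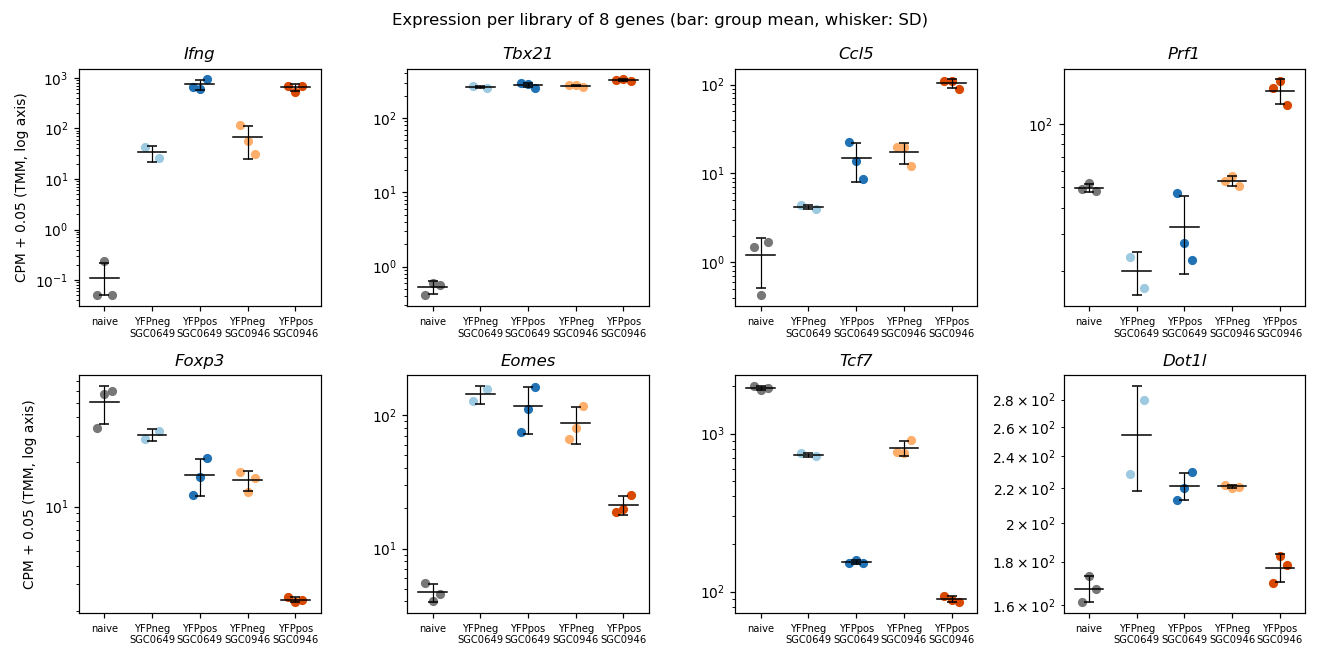
CPM (TMM-scaled, plus 0.05, log axis) of 8 genes in each of the 14 libraries, by group; points are libraries, horizontal bars are group means and whiskers are SD. Ifng separates YFPpos from YFPneg libraries, Tbx21 is near 265 to 322 CPM in the 4 cultured groups, and Foxp3 is lowest in YFPpos SGC0946 cells at 2.31 CPM.

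The first comparison, YFPpos SGC0649 against naive cells, asks what Th1 culture with the control compound changed in interferon-gamma producers. All 28 tested cell cycle genes, 24 of 26 Th1 genes and 17 of 18 glycolysis genes were higher in these cells, and 18 of 21 naive genes were lower. Ifng was at 3 counts in all naive libraries together and was 12440-fold higher in YFPpos cells (95% counting interval 4257 to 60330). Tbx21 rose by 9.18 (SE 0.11) on the log2 scale, and Gzmb, the protease of cytotoxic granules, by 11.16 (SE 0.19). Genes with no count in naive cells included Ccl4, a chemokine made by activated T cells, at least 4834-fold higher, and Batf3, an AP-1 family transcription factor, at least 663.8-fold higher. Gstt1, a glutathione transferase, was at least 564.4-fold higher, Tnip3, an inhibitor of NF-kappaB signalling, at least 531.7-fold, and Perp, a p53 target, at least 529.4-fold.

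Among genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest falls were in Slc16a5, a monocarboxylate transporter, with a log2 fold change of -10.21 (SE 0.30), and Dtx1, a Notch pathway gene, with -8.38 (SE 0.22). They were followed by the pyrin domain gene Pydc4 (-8.23), BC106179 (-8.10), the sialyltransferase St8sia6 (-7.49) and Gm14085 (-7.35). Among lineage regulators, Gata3, the Th2 regulator, had -1.78 (SE 0.13) and Foxp3, which defines regulatory T cells, -1.63 (SE 0.20). Their lists did not follow them. Adjusted over all genes, 10 of 15 Th2 genes rose and 4 fell, and 9 of 14 genes of regulatory T cells rose and 3 fell. Dot1l, the gene of the inhibitor's target (ENSMUSG00000061589, chromosome 10, 80755206 to 80795461), rose by 0.40 (SE 0.07), from 167 CPM ± 5.92 (SD, n = 3) to 221 ± 8.29 (n = 3).

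By list, the cell cycle genes rose together (camera adjusted p 5.7e-67; adjusted p = 3.1e-05 with an estimated correlation), among them Mki67, a marker of dividing cells (7.69), and Top2a, a topoisomerase of replicating DNA (7.14). Of 26 Th1 programme genes 24 rose, including Bhlhe40 (9.20) and the IL-12 receptor chain Il12rb2 (9.60), while Stat4, which signals from that receptor, fell by 0.35 on the log2 scale (camera adjusted p 5.5e-15; 0.022 with an estimated correlation). Of 18 glycolysis genes 17 rose, such as Hk2 (8.96) and Ldha (2.54), and Pdk1, a kinase that restrains pyruvate oxidation, had -2.34 (camera adjusted p 1.3e-14; adjusted p = 0.12 with an estimated correlation). Of 15 cytotoxic and NK receptor genes 13 rose, including Cst7 (4.03), and Prf1, which encodes perforin, had -0.62 (camera adjusted p 9.2e-05; adjusted p = 0.21 with an estimated correlation). Of 21 naive and quiescence genes 18 fell, such as Klf3 (-4.70) and Tcf7 (-3.66), a factor of naive and memory cells. Satb1 (0.35) and the lymph node homing receptor Ccr7 (0.32) rose (camera adjusted p 2.5e-12; 0.022 with an estimated correlation). The interferon response list split, with 11 of 30 genes higher and 15 lower (camera adjusted p 0.52; 0.91 with an estimated correlation). In all, 9854 of 12343 genes passed the edgeR test, 5256 higher and 4598 lower, of which 3129 and 2267 changed at least 2-fold. The comparison joins polarization, activation and 4 days of culture with the difference between sorted naive and enriched starting cells. All 4 tested genes of the sex-linked list were lower than in naive cells, adjusted over all genes. Of these, 2 were also lower in YFPpos than in YFPneg SGC0649 cells, and the cause was not tested.

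The second comparison, YFPneg SGC0649 against naive cells, asks what the same culture changed in cells that did not report interferon-gamma. YFPneg cells too had high Tbx21 and cell cycle transcripts. Tbx21 rose by 9.10 (SE 0.12) on the log2 scale, and Ifng, at 3 counts in naive cells, was 568.3-fold higher (95% counting interval 194.1 to 2759). Of 30 interferon response genes 26 were higher, as were 14 of 18 early response genes of the T cell receptor. Irf8, a transcription factor induced by interferon-gamma, rose by 5.86 (SE 0.09), and Irf4, induced by T cell receptor signals, by 6.90 (SE 0.09).

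Genes without a count in naive cells again included Ccl4, at least 1548-fold higher, Gstt1, at least 412.2-fold, and Tnip3, at least 353.9-fold. Serpinb5, a serpin, was at least 273.7-fold higher, Cetn4, a centrin, at least 268.1-fold and Ly6g, a surface antigen known from neutrophils, at least 241.5-fold, though the adjusted p of Ly6g was 0.072 by limma-voom (1.1e-11 to 0.072 over its alternatives). Within the same limits on level and overlap, the largest falls were Slc16a5 (-6.62, SE 0.26), Dtx1 (-5.80, SE 0.21), Fam101b (-5.22, SE 0.12) and Hsd11b1, which activates glucocorticoids (-4.50, SE 0.25). The mitochondrial genes mt-Atp6 (-4.96, SE 0.62) and mt-Co3 (-4.70, SE 0.62) also fell, but their sequence is shared almost entirely with annotated nuclear copies. Gata3 had -1.02 (SE 0.14) and Dot1l 0.61 (SE 0.07; adjusted p 1.1e-06). Adjusted over all genes, 7 of 15 Th2 genes rose and 4 fell, and 9 of 14 genes of regulatory T cells rose and 2 fell. Foxp3 had -0.72 (SE 0.22; adjusted p 0.0085), which became 0.077 without YFPneg SGC0649 replicate 1 (0.00053 to 0.077 over its alternatives).

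All 28 cell cycle genes rose (camera adjusted p 2.6e-89; 1.5e-05 with an estimated correlation), as did 24 of 26 Th1 genes, while Stat4 had -0.72 (camera adjusted p 2.6e-19; 0.012 with an estimated correlation). Of 30 interferon response genes 26 rose, among them the GTPases Gbp5 (4.78) and Gbp2 (5.10), and Irf9, part of the type I interferon signal, had -0.52 (camera adjusted p 3.1e-14; adjusted p = 0.096 with an estimated correlation). Of 18 T cell receptor early response genes 14 rose, including Nr4a1 (3.43) and Nr4a2 (7.45), orphan nuclear receptors induced by antigen receptor signals (camera adjusted p 1.2e-11; 0.012 with an estimated correlation). The phosphatase gene Dusp2 had -0.33, and its adjusted p of 0.018 became 0.12 without YFPneg SGC0649 replicate 1 and 0.072 without naive replicate 3 (0.0021 to 0.12 over its alternatives). The edgeR test called 8518 genes, 4494 higher and 4024 lower, with 2328 and 1445 at least 2-fold. Only 2 YFPneg libraries entered. In these 3.44% to 4.41% of reads were unmapped, against 7.404% to 8.655% in naive libraries. Such a library difference cannot be told apart from the effect of culture. The difference between sorted naive and enriched starting cells enters here too. All 4 tested sex-linked genes were again lower than in naive cells, adjusted over all genes.

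**Figure D2:**
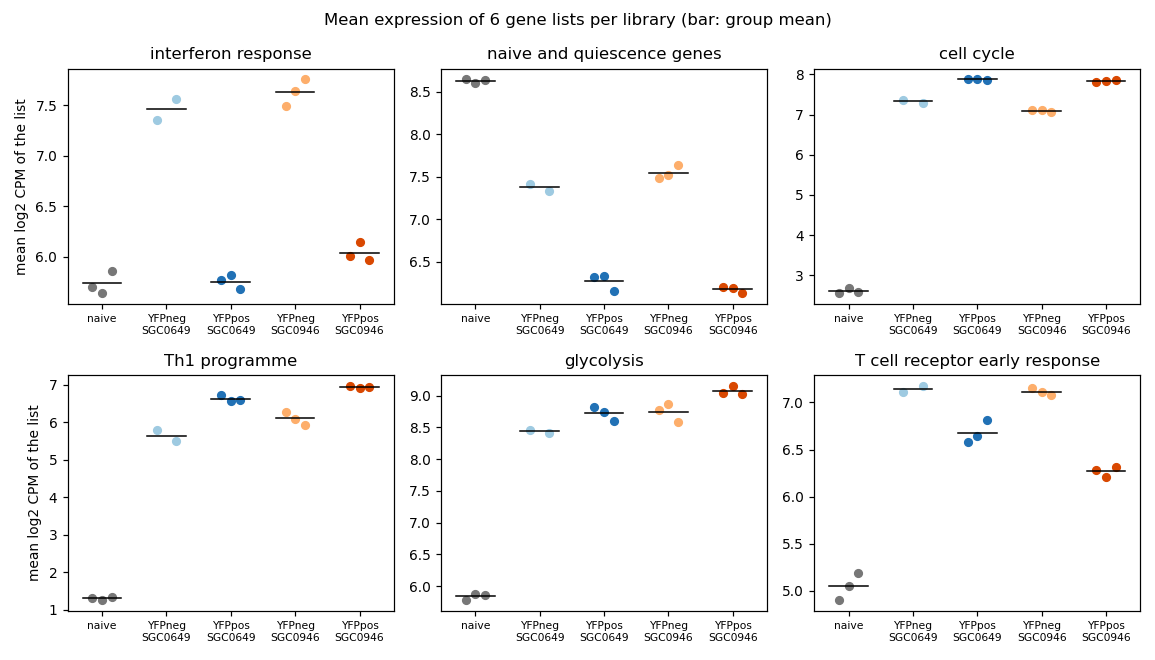
Mean log2 CPM of the tested members of 6 gene lists in each of the 14 libraries, by group; points are libraries. The interferon response list is lower in YFPpos than in YFPneg libraries with either compound, and the cell cycle list, whose 28 members rose in culture, is lowest in naive libraries.

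The third comparison, YFPpos against YFPneg cells of the SGC0649 cultures, asks how interferon-gamma producers differ from the other cells of these cultures. Producers had lower levels of 27 of 30 interferon response genes and of 19 of 21 naive genes, and higher levels of 23 of 28 cell cycle genes. Ifng was 21.8-fold higher (log2 fold change 4.45, SE 0.40, adjusted p 1.9e-07), while Tbx21 differed by 0.08 (95% interval -0.06 to 0.22, adjusted p 0.32). Xcl1, a chemokine that attracts cross-presenting dendritic cells, rose by 3.92 (SE 0.42), from 7.15 CPM in YFPneg to 108 ± 57.4 (SD, n = 3) in YFPpos cells. Irf7, a central interferon response factor, stood at 103 CPM in YFPneg and 6.36 in YFPpos cells (-4.02, SE 0.15), and Tcf7 at 734 and 154 CPM (-2.26, SE 0.07).

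Other large rises were Il1rl1, the IL-33 receptor (4.00, SE 0.33), and Batf3 (3.67, SE 0.35). Within the same limits on level and overlap, the largest falls were BC106179 (-6.11, SE 0.54), the antiviral genes Oasl2 (-5.41), Oas2 (-5.30) and Rtp4 (-5.10), and the pyrin domain genes Pydc4 (-6.07) and Pydc3 (-4.95). The uncertain mitochondrial genes mt-Co3 (4.22, SE 0.62) and mt-Atp6 (3.94, SE 0.63) were higher. Gata3 had -0.76 (SE 0.14; adjusted p 0.00039), or -0.49 without YFPneg SGC0649 replicate 1, and Foxp3 had -0.90 (SE 0.22; adjusted p 0.0034). Adjusted over all genes, 7 of 15 Th2 genes rose and 3 fell, and 7 of 14 genes of regulatory T cells rose and 3 fell. Dot1l had -0.20 (SE 0.07; adjusted p 0.032), which became 0.63 without YFPneg SGC0649 replicate 2, at a log2 fold change of -0.05, and 0.089 and 0.072 without YFPpos SGC0649 replicates 1 and 2 (0.0015 to 0.63 over its alternatives).

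Of 30 interferon response genes 27 fell, including Ifit3 (-4.50) and the GTPase gene Irgm1 (-1.83), and Irf8 rose by 0.52 (camera adjusted p 1.7e-46; 0.0095 with an estimated correlation). Of 21 naive and quiescence genes 19 fell, such as Klf3 (-1.84) and the egress receptor S1pr1 (-2.12) (camera adjusted p 7.8e-23; 0.0072 with an estimated correlation). Of 28 cell cycle genes 23 rose, among them the mitotic genes Cdc20 (1.22), Aurka (1.18) and Birc5 (0.93) (camera adjusted p 1.6e-12; 0.0075 with an estimated correlation). Of 26 Th1 genes 19 rose, including the chemokine Ccl3 (2.52) and the granule gene Nkg7 (1.75), while the IL-12 receptor chain Il12rb1 (-0.57) was among those that fell (camera adjusted p 0.00027; adjusted p = 0.18 with an estimated correlation). Of 15 cytotoxic and NK receptor genes 11 rose, including Gzmb (1.09) and the receptor gene Klrk1 (2.93) (camera adjusted p 0.0016; adjusted p = 0.33 with an estimated correlation). Of 5 NK cell markers Klri2 (3.17), Klre1 (2.09) and Klra7, at 0 counts in YFPneg cells and at least 6.03-fold higher, also rose (camera adjusted p 0.25; adjusted p = 0.56 with an estimated correlation). The adjusted p of Klre1, 0.010, became 0.096 without YFPneg SGC0649 replicate 2 (0.0022 to 0.096 over its alternatives), and that of Klra7, 0.018, became 0.086 and 0.082 without YFPneg SGC0649 replicates 1 and 2 (0.0081 to 0.086). Of 18 T cell receptor early response genes 11 fell, including Nr4a1 (-1.16), Egr1 (-0.88) and Cd69 (-0.91), while Irf4 rose by 0.28 (camera adjusted p 0.00027; adjusted p = 0.15 with an estimated correlation). In all, 5585 genes passed the edgeR test, 2955 higher and 2630 lower, with 625 and 618 at least 2-fold. A block by the numbers in the sample titles left 4342 genes, 2129 higher and 2213 lower. With SGC0649, 3.44% to 4.41% of reads were unmapped in YFPneg and 6.44% to 8.35% in YFPpos libraries. A library difference that goes with the sort cannot be told apart from the sort in these counts.

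The fourth comparison asks the same of the SGC0946 cultures. With the inhibitor, 28 of 30 interferon response genes and 19 of 21 naive genes were lower in producers, 26 of 28 cell cycle genes were higher, and 13 of 18 early response genes of the T cell receptor were lower. Ifng was 9.55-fold higher in YFPpos cells (log2 fold change 3.26, SE 0.32). Foxp3 was at 2.31 CPM ± 0.0881 (SD, n = 3) in YFPpos and 14.9 ± 2.31 (n = 3) in YFPneg cells (-2.69, SE 0.25). Tbx21 rose by 0.24 (SE 0.06; adjusted p 0.0027) and Batf3 by 3.11 (SE 0.26). Gata3 had -1.35 (SE 0.13) and Dot1l -0.32 (SE 0.07; adjusted p 0.00059). Adjusted over all genes, 6 of 15 Th2 genes rose and 3 fell, and 6 of 14 genes of regulatory T cells rose and 4 fell.

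Within the same limits on level and overlap, the largest falls were Rtp4 (-5.98, SE 0.26), Pydc4 (-5.84, SE 0.17), Pydc3 (-5.82, SE 0.20), Oas2 (-5.67, SE 0.20) and Ifit3 (-5.10, SE 0.21). BC106179, at 3 counts in the YFPpos libraries together, was 280.6-fold higher in YFPneg cells (95% counting interval 95.5 to 1365). Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, had 3.42 (SE 0.28). As CPM of the library total Lars2 stood at 1211 to 1519 in naive, 66.9 to 164 in YFPneg and 685 to 1282 in YFPpos libraries. No sequence shared with another annotated transcript was found for Lars2, and the reason for its pattern stays open. The uncertain genes mt-Co3 (4.15, SE 0.54), mt-Atp6 (3.92, SE 0.54) and mt-Co2 (3.17, SE 0.47) were higher in YFPpos cells. YFPpos SGC0946 replicate 2, the library with fewer unmapped reads, had 7.03 CPM of mt-Co3 against 38.0 and 39.1 in the other libraries of its group, while its Lars2, at 1031 CPM, was not low.

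Of 30 interferon response genes 28 fell, or 27 with DESeq2 size factors, including Irf7 (-3.84) and Iigp1 (-2.20) (camera adjusted p 8.6e-31; 0.032 with an estimated correlation). Of 21 naive and quiescence genes 19 fell, such as Tcf7 (-3.18), Klf3 (-2.53) and Bach2 (-1.51), a repressor of effector genes (camera adjusted p 6.4e-28; 0.0024 with an estimated correlation). The survival receptor gene Il7r had 0.53 (adjusted p 0.020), which became 0.070 without YFPneg SGC0946 replicate 2 and 0.055 without YFPpos SGC0946 replicate 2 (3.9e-06 to 0.088 over its alternatives). Of 18 T cell receptor early response genes 13 fell, including Nr4a1 (-2.01), Egr1 (-1.46) and the activation marker Cd69 (-2.02) (camera adjusted p 1.4e-07; 0.034 with an estimated correlation). Of 28 cell cycle genes 26 rose (camera adjusted p 7.3e-19; 0.0024 with an estimated correlation). Of 26 Th1 genes 20 rose, or 21 adjusted over the list alone, while Eomes (-2.04), Cxcr3 (-1.08), Stat4 (-0.42) and Il12rb1 (-0.33) were among those that fell (camera adjusted p 0.0016; adjusted p = 0.24 with an estimated correlation). Of 5 NK cell markers Klri2 (3.06) and Klre1 (1.84) rose (camera adjusted p 0.30; adjusted p = 0.55 with an estimated correlation). The edgeR test called 6752 genes, 3321 higher and 3431 lower, with 948 and 744 at least 2-fold, and 6219 with a block by the numbers in the sample titles. With DESeq2 size factors most called genes were higher instead, 3716 against 3048 lower. Across all 12343 genes the reporter fold changes with the 2 compounds had a Pearson r of 0.713 and a Spearman rho of 0.789, although genes are not independent replicates. Of 4671 genes called with both compounds, 4660 changed in the same direction.

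The fifth comparison, SGC0946 against SGC0649 in YFPpos cells at the same dose and day, asks what the inhibitor changed in interferon-gamma producers. Ifng itself did not pass the test, at 645 CPM with SGC0946 and 737 with SGC0649 (log2 fold change -0.19, 95% interval -0.79 to 0.41, adjusted p 0.66). Both groups had been sorted as reporter-positive after treatment. Their Ifng levels therefore cannot tell whether SGC0946 changed Ifng in the whole culture or the share of producers. For other genes, a change in which cells were sorted as YFPpos cannot be told apart from a change within cells. Of 15 cytotoxic genes 10 rose and of 18 glycolysis genes 14, and 6 of 14 genes of regulatory T cells fell, or 11, 16 and 7 adjusted over each list alone. Prf1, the pore-forming perforin, rose from 32.2 CPM ± 13 (SD, n = 3) to 144 ± 19.1 (n = 3), a log2 fold change of 2.16 (SE 0.19, adjusted p 1.2e-06). Ccl5, a chemokine of effector T cells (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), was 6.89-fold higher, at 103 CPM ± 11.4 (SD, n = 3) against 14.96 ± 7.05 (n = 3).

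Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) was 7.03-fold lower, at 2.31 CPM ± 0.0881 (SD, n = 3) against 16.2 ± 4.59 (n = 3), with an adjusted p of 1.1e-06. Tbx21 rose by 0.20 (SE 0.06; adjusted p 0.017), and this adjusted p became 0.10 without YFPpos SGC0649 replicate 3 and 0.074 without YFPpos SGC0946 replicate 2 (0.0011 to 0.10 over its alternatives). Gata3 had -0.51 (SE 0.13; adjusted p 0.0090), or 0.051 without YFPpos SGC0946 replicate 3, with 0.0060 to 0.051 over its alternatives. Dot1l had -0.32 (SE 0.07; adjusted p 0.0020), at 177 CPM ± 6.67 (SD, n = 3) against 221 ± 8.29 (n = 3).

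Among genes with a mean log2 CPM of at least 3 and no overlap between the groups, the largest rises after Ccl5 were in Gpnmb, a surface glycoprotein (2.77, SE 0.33), the metallothionein Mt2 (2.58, SE 0.42), Ly6g (2.48, SE 0.54), the laminin-binding integrin Itga7 (2.48, SE 0.31) and the cytochrome P450 Cyp2s1 (2.46, SE 0.22). The largest falls within these limits were Lad1, an anchoring filament protein (-3.11, SE 0.38), Foxp3 (-2.81, SE 0.25), Eomes, a T-box factor of effector cells (-2.46, SE 0.24), the phospholipase Pla2g4f (-2.22, SE 0.19), Xcl1 (-2.19, SE 0.31) and the actin-severing protein Scin (-2.09, SE 0.40).

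Of 18 glycolysis genes 14 rose, or 16 adjusted over the list alone, including the glucose transporter Slc2a3 (1.18) and the lactate transporter Slc16a3 (0.67) (camera adjusted p 3.2e-07; adjusted p = 0.32 with an estimated correlation). Of 15 cytotoxic and NK receptor genes 10 rose, or 11 adjusted over the list alone, including Fgl2 (2.20), while Crtam (-1.59) and the granzyme inhibitor Serpinb9 (-0.71) fell (camera adjusted p 0.00016; adjusted p = 0.32 with an estimated correlation). Of 26 Th1 genes 12 rose, or 14 adjusted over the list alone, such as Ccl5, Id2 (1.06) and Prdm1 (1.79), the gene of the effector regulator Blimp-1, and 6 fell, such as Eomes (camera adjusted p 0.0064; adjusted p = 0.42 with an estimated correlation). Of 14 Treg genes 6 fell, or 7 adjusted over the list alone, including Lrrc32 (-1.48), which presents latent TGF-beta, and Gpr83 (-1.47), while Ctla4 rose by 0.46 (camera adjusted p 0.0064; adjusted p = 0.44 with an estimated correlation).

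Of 18 T cell receptor early response genes 12 fell, including Nr4a3 (-1.24), Nr4a1 (-0.98) and Cd69 (-1.11), while Tnfaip3 (0.37) and Junb (0.28) rose, with 3 risers adjusted over the list alone (camera adjusted p 0.0002; adjusted p = 0.25 with an estimated correlation). Of 30 interferon response genes 12 rose, or 13 adjusted over the list alone, and Irf8 (-0.31) and Iigp1 (-0.29) fell (camera adjusted p 0.0005; adjusted p = 0.44 with an estimated correlation). The adjusted p of Iigp1, 0.017, became 0.10 without YFPpos SGC0649 replicate 3 and 0.077 without YFPpos SGC0946 replicate 3 (0.0075 to 0.10 over its alternatives). Of 16 adhesion and migration genes 7 rose, such as the chemokine receptors Cxcr4 (2.12) and Ccr2 (2.11), while Ccr7 had -0.69 (camera adjusted p 0.0005; adjusted p = 0.25 with an estimated correlation). Of 28 cell cycle genes 23 did not pass the test, or all 28 adjusted over the list alone (camera adjusted p 0.53).

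Of the 7 tested B cell marker genes, the MHC class II genes H2-Ab1 (2.02), H2-Aa (2.75) and H2-Eb1 (2.34), the invariant chain Cd74 (0.93) and the transcription factor Ebf1 (1.84) rose (camera adjusted p 3.3e-05; adjusted p = 0.25 with an estimated correlation and 0.17 with no filter on low counts). For Ebf1 the adjusted p of 0.026 became 0.064 to 0.098 without any single one of the 6 YFPpos libraries, within 0.00070 to 0.098 over all its alternatives. The B cell receptor genes Cd79a, at 0.257 CPM of the library total with SGC0946 and 0.197 with SGC0649, and Cd79b, at 0.0499 and 0.0468, stayed close to the floor.

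In all, 3424 genes passed the edgeR test, 1490 higher and 1934 lower, of which 605 and 67 changed at least 2-fold, or 346 and 46 without YFPpos SGC0649 replicate 3 and 395 and 52 without YFPpos SGC0946 replicate 2. The share of higher genes among those called was 43.5%, and 55.1% with DESeq2 size factors, where 1702 of 3090 were higher. Without YFPpos SGC0649 replicate 3 the count was 1886 and without YFPpos SGC0946 replicate 2 it was 2004. Camera called 9 of the 25 lists, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, while fry called 15.

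**Figure D3:**
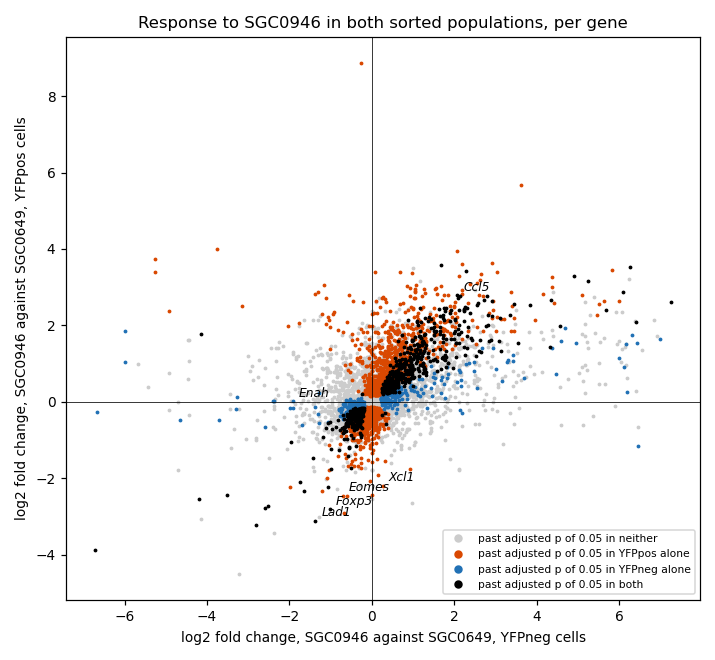
Log2 fold change of SGC0946 against SGC0649 in YFPneg cells (x axis) and in YFPpos cells (y axis) for the 12343 genes tested; each point is a gene, coloured by whether it passed an adjusted p of 0.05 in both populations, in one alone or in neither. Ccl5 lies high on both axes (2.07 and 2.78), and Foxp3 lies further down in YFPpos (-2.81) than in YFPneg cells (-1.02).

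The sixth comparison asks what SGC0946 changed in YFPneg cells. Ccl5 and Prf1 were higher, Foxp3 was lower, and 10 of 28 cell cycle genes fell, or 18 adjusted over the list alone. Ccl5 rose by 2.07 (SE 0.36) and Prf1 by 1.43 (SE 0.23). Foxp3 had -1.02 (SE 0.23; adjusted p 0.013), or 0.096 without YFPneg SGC0649 replicate 2 (0.0011 to 0.096 over its alternatives), and Lrrc32 had -1.43 (SE 0.22).

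Ifng, Tbx21, Gata3 and Dot1l did not pass the test. YFPneg cells, too, were sorted on the reporter after treatment, so the same limits hold as in YFPpos cells. Ifng was at 66.8 CPM ± 42.5 (SD, n = 3) against 33.8 ± 11.8 (n = 2), a log2 fold change of 1.00 (95% interval 0.23 to 1.77, adjusted p 0.094). Without YFPneg SGC0946 replicate 3 its log2 fold change was 1.33 and its adjusted p 0.0094, and with no filter on low counts its adjusted p was 0.035, within 0.0090 to 0.42 over its alternatives. Tbx21 differed by 0.05 (95% interval -0.09 to 0.19, adjusted p 0.67) and Gata3 by 0.08 (SE 0.14, adjusted p 0.76). Dot1l had -0.20 (SE 0.07, adjusted p 0.089), or -0.34 and 0.014 without YFPneg SGC0649 replicate 1 (0.014 to 0.72 over its alternatives).

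Within the same limits on level and overlap, the largest rises were Vldlr, a lipoprotein receptor (3.12, SE 0.30), Serpinf1, a secreted serpin (2.39, SE 0.39), the ubiquitin hydrolase Uchl1 (2.33, SE 0.24), Itga7 (2.27, SE 0.35), the activation receptor Tnfrsf8, known as CD30 (2.25, SE 0.41), and the membrane protein Emp1 (2.24, SE 0.27). The largest falls within these limits were Enah, an actin regulator (-1.92, SE 0.39), Scin (-1.75, SE 0.50), Lrrc32, Lad1 (-1.37, SE 0.38), Socs2, a brake on cytokine signals (-1.31, SE 0.15), and the cytokine Lta (-1.19, SE 0.25). Without YFPneg SGC0649 replicate 2 the adjusted p became 0.074 for Tnfrsf8, 0.067 for Enah, 0.19 for Scin, 0.33 for Lad1, at a log2 fold change of -0.80, and 0.14 for Lta. Scin also reached 0.068 without YFPneg SGC0649 replicate 1 and 0.060 without YFPneg SGC0946 replicate 2, and Lad1 reached 0.066 and 0.086 without YFPneg SGC0946 replicates 1 and 2. The lowest adjusted p over the alternatives was 0.00012 for Tnfrsf8, 0.00050 for Enah, 0.011 for Scin, 0.0021 for Lad1 and 0.00084 for Lta, and the values without YFPneg SGC0649 replicate 2 were the highest.

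Of 28 cell cycle genes 10 fell, or 18 adjusted over the list alone, including the thymidylate synthase Tyms (-0.49), the mitotic kinase Cdk1 (-0.35) and Foxm1 (-0.35) (camera adjusted p 3.9e-10; 0.030 with an estimated correlation). In a fit to the compared groups alone these 3 had adjusted p of 0.071, 0.13 and 0.13, the highest over their alternatives, which start at 0.00024, 0.00013 and 0.00093. Of 18 glycolysis genes 8 rose, or 14 adjusted over the list alone (camera adjusted p 7.8e-08; adjusted p = 0.23 with an estimated correlation). Of 15 cytotoxic and NK receptor genes 7 rose, or 10 adjusted over the list alone (camera adjusted p 1.2e-05; adjusted p = 0.13 with an estimated correlation). Of the 2 tested CD8 T cell markers, Cd8b1 rose by 0.84 (SE 0.22), at 13.6 CPM of the library total against 7.63, while Cd8a, at 1.26 against 0.439, did not pass (1.51, or 0.68 without YFPneg SGC0946 replicate 3; adjusted p 0.30, with 0.086 to 0.66 over its alternatives). The adjusted p of Cd8b1, 0.026, became 0.17 without YFPneg SGC0649 replicate 1 (0.0055 to 0.17 over its alternatives). Across the groups Cd8b1 was highest in sorted naive CD4+ cells, at 16.9 CPM of the library total, where Cd8a was at 0.191. The rise of Cd8b1 alone therefore does not point to CD8 T cells. Of 26 Th1 genes 9 rose and Lta fell, or 15 rose and 2 fell adjusted over the list alone. They included Ccl4 (0.91) and Ccl5 (camera adjusted p 2.8e-05; adjusted p = 0.13 with an estimated correlation). Of 15 Th2 genes 6 rose, among them Maf (1.74), a transcription factor of cytokine genes, and Ccr8 fell adjusted over the list alone (camera adjusted p 0.0014; adjusted p = 0.13 with an estimated correlation).

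In all, 1065 genes passed the edgeR test, 616 higher and 449 lower, with 247 and 37 at least 2-fold. The counts at least 2-fold were 115 and 17 without YFPneg SGC0649 replicate 2, and 265 and 85, 257 and 60, and 429 and 43 without YFPneg SGC0946 replicates 1, 2 and 3. The count was 335 without YFPneg SGC0649 replicate 2 and 199 in a fit to the compared groups alone. Across all 12343 genes the SGC0946 fold changes in YFPpos and YFPneg cells had a Pearson r of 0.497 and a Spearman rho of 0.541. Of 703 genes called in both, 431 were higher and 267 lower in both, and 5 went opposite ways. Whether YFPpos and YFPneg libraries with the same number came from 1 culture is not given in the sources used here, so the fold changes in the 2 populations are not taken as independent.

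The seventh comparison, the interaction, tests whether the effect of SGC0946 differed between YFPpos and YFPneg cells. Cells were sorted after treatment. A changed response within cells therefore cannot be told apart from a change in which cells fell in each sort. The naive genes Tcf7, Bach2, Ccr7 and Foxp1 and the early response gene Nr4a1 had lower fold changes with SGC0946 in YFPpos than in YFPneg cells. The difference was -0.92 for Tcf7 (adjusted p 0.00075), -0.81 for Bach2, -0.75 for Ccr7, -0.67 for Foxp1 and -0.85 for Nr4a1. Cd74 had a higher fold change in YFPpos cells, with a difference of 1.07 (adjusted p 0.0068). Ifng had a difference of -1.19 (SE 0.46, adjusted p 0.26), or -1.52 with an adjusted p of 0.046 without YFPneg SGC0946 replicate 3 (0.046 to 0.52 over its alternatives). For Tbx21 the difference was 0.15 (adjusted p 0.47), for Gata3 -0.59 (0.18) and for Dot1l -0.12 (0.65).

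Of 21 naive and quiescence genes Tcf7, Bach2, Ccr7, Foxp1 and Klf3 (-0.68) had a negative interaction and S1pr1 (0.82) a positive one, or 10 and 1 adjusted over the list alone (camera adjusted p 1.6e-07; adjusted p = 0.079 with an estimated correlation). Of 18 T cell receptor early response genes Nr4a1, Egr1 (-0.59), Cd69 (-1.10) and Nr4a3 (-0.96) were negative, or 7 adjusted over the list alone (camera adjusted p 3.5e-06; adjusted p = 0.079 with an estimated correlation). Of 7 B cell marker genes Cd74 and H2-Eb1 (3.26) were positive, or 4 adjusted over the list alone (camera adjusted p 3.1e-06; adjusted p = 0.079 with an estimated correlation). In all, 142 genes passed the edgeR test, 32 positive and 110 negative, and 22.5% were positive, or 32.8% with DESeq2 size factors. The count was 56 in a fit to the compared groups alone and 300 by the DESeq2 Wald test. It was 61 and 76 without YFPneg SGC0649 replicates 1 and 2, 241 without YFPneg SGC0946 replicate 2, 71 without YFPpos SGC0649 replicate 2, and 66, 86 and 78 without YFPpos SGC0946 replicates 1, 2 and 3. Without YFPneg SGC0649 replicate 1 the adjusted p became 0.065 for Klf3, 0.063 for S1pr1, 0.053 for Egr1, 0.091 for Cd69, 0.091 for Nr4a3 and 0.065 for H2-Eb1. Without YFPneg SGC0649 replicate 2, YFPpos SGC0649 replicate 2 or a single YFPpos SGC0946 library, Cd69, Nr4a3, S1pr1 or Klf3 also missed the threshold, at adjusted p from 0.051 to 0.083. Over all alternatives the lowest adjusted p was 0.00079 for Klf3, 4.6e-05 for S1pr1, 7.4e-05 for Egr1, 0.00038 for Cd69, 0.00077 for Nr4a3 and 2.8e-05 for H2-Eb1, and the highest was 0.105 for Klf3 in a fit to the compared groups alone.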

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

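The tests for naive cells among the sorted YFPneg cells and for mitochondrial RNA as a whole, and the look at mt-Atp8, mt-Nd3, mt-Nd4l and genes of middle expression, were chosen only after the results were seen, and the other tests of this part were written before.

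The effect of SGC0946 differed between YFPpos and YFPneg cells for 142 genes by the interaction term of the edgeR model, a count that with 1 library left out lay between 61 (without YFPneg SGC0649 replicate 1) and 241 (without YFPneg SGC0946 replicate 2). It was 56 in a fit to the compared groups alone and 300 by the DESeq2 Wald test. The values are log2 differences, the effect in YFPpos minus that in YFPneg cells. Because cells were sorted after treatment, these differences cannot separate a response within cells from a change in which cells fell in each sort. Foxp3, the regulatory T cell factor, had -1.79, and its adjusted p of 0.015 became 0.075 and 0.0502 without YFPneg SGC0649 replicates 1 and 2 and 0.11 by limma-voom (7.5e-05 to 0.11 over its alternatives). Of 21 naive and quiescence genes 5 were negative, Tcf7 at -0.92, Bach2 at -0.81, Ccr7 at -0.75, Foxp1 at -0.67 and Klf3 at -0.68, S1pr1 was positive at 0.82 and 15 did not pass, with 10 negative and 1 positive adjusted over the list alone. Of 18 T cell receptor early response genes 4 were negative, Nr4a1 at -0.85, Egr1 at -0.59, Cd69 at -1.10 and Nr4a3 at -0.96, and 14 did not pass, with 7 negative adjusted over the list alone. With an estimated correlation neither list was called (adjusted p = 0.079 for each). Other negative values were Xcl1 at -2.46, Eomes at -1.75, the adhesion receptor Cd226 at -1.62, the TNF family ligand Tnfsf8 at -1.34 and the aldo-keto reductase Akr1c13 at -1.25. Positive values were Apol7e at 1.47, the Notch ligand Jag2 at 1.27, the antiviral membrane protein Ifitm3 at 1.17, Cd74 at 1.07, the serpin Serpina3g at 1.07, Cxcr4 at 1.02 and the MHC class II gene H2-Eb1 at 3.26. Of these, Tcf7, Bach2, Ccr7, Foxp1, Nr4a1 and Cd74 stayed past the threshold in all 20 alternatives. Each of the others missed it without YFPneg SGC0649 replicate 1 or 2, and each of the other 9 cultured libraries, left out alone, ended at least 1 call, most often that of Cxcr4 or Serpina3g. Adjusted p reached 0.16 for Cxcr4 and Serpina3g and 0.13 for Xcl1 and Jag2 with 1 library left out.

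Changes of at least 2-fold with SGC0946 in YFPpos cells were mostly increases, 605 against 67, or 346 against 46 without YFPpos SGC0649 replicate 3 and 395 against 52 without YFPpos SGC0946 replicate 2. Scaling would have to shift every gene by 0.499 on the log2 scale to make them even. The median change of all genes was -0.04. However, TMM scaling had already set the bulk of genes near no change. The median therefore cannot show a shift that all genes share, and it does not decide about scaling. After thinning to the smallest library total, 89.33% of these changes were still increases. Genes were ranked by their mean in the YFPneg SGC0649 libraries, which are not part of this comparison. Genes near the floor cannot fall far, and the share fell with level, to 68.33% among the 4114 genes in the middle (41 against 19, 95% interval 55.0 to 79.7). It was 58.33% among the 4114 most highly expressed genes (14 against 10, 95% interval 36.6 to 77.9). For SGC0946 in YFPneg cells, with genes ranked by YFPpos SGC0649 means, the share was 87.72% among the least expressed and 86.36% among the middle genes. It was 75% among the most highly expressed genes there (9 against 3, 95% interval 42.8 to 94.5). Among the 4115 least expressed genes in the YFPpos comparison, those at 5 CPM or more still showed 82.76% increases (72 against 15, 95% interval 73.2 to 90.02). Such genes can still lie near the floor in the YFPpos SGC0649 cells compared, so this share does not decide about the floor. Under 5 CPM (478 against 23) the floor stays open too. A gain of weakly expressed genes through the inhibitor may account for part of the pattern, as a hypothesis that was not tested separately.

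Interferon response genes were lower in YFPpos than in YFPneg cells. Depth does not account for it, since 27 of 30 members were called lower after thinning. Naive cells left among the YFPneg cells would leave the members between the levels of naive and YFPpos cells, but 23 of the 27 members that fell were higher in YFPneg than in naive cells. A difference in interferon signalling between producers and other cells may remain as a hypothesis. Less activated cells other than naive ones in the YFPneg fraction stay open. With SGC0649, 19 of 21 naive genes, among them Tcf7 and Klf3, were higher in YFPneg cells, and 23 of 28 cell cycle genes were lower. Both lists were also called with an estimated correlation. Going the other way, 11 of 18 T cell receptor early response genes were higher in YFPneg cells, but that list was not called with an estimated correlation.

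The mitochondrial genes mt-Co2, mt-Atp6 and mt-Co3 were low in YFPneg libraries, and also in YFPpos SGC0946 replicate 2, a library that shares its low share of unmapped reads (3.61%) with the YFPneg libraries. At least 99.51% of the 75-base stretches of each occur in an annotated nuclear copy, against at most 61.5% for the other 6 mitochondrial genes above 500 CPM. Weaker genes do not all follow this: mt-Atp8, with 0% of its stretches in another annotated transcript, had 3.50 to 4.58 CPM in naive, 0 to 0.069 in YFPneg and 0.691 in that YFPpos library, while mt-Nd3, with 97.81%, had 2.97 CPM there, against 3.35 and 2.94 in the other libraries of its group, and mt-Nd4l, with 98.65%, had 0.244. Shared sequence therefore stays open for the 3 genes, because copies without an annotation were not searched, and for Lars2, with 0% and 1031 CPM in that YFPpos library, it was not found. The 6 genes above 500 CPM had a median log2 fold change of -0.1975 (-0.46 to 0.05) in YFPpos against YFPneg cells with SGC0649, which argues against a change of mitochondrial RNA as a whole.

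In 3 comparisons of 3 against 3 libraries the real grouping was set against the other 9 of 10 splits, and only 1 of the 10, the real one, gave as many genes. The real counts were 9854 for YFPpos SGC0649 against naive cells, 6752 for YFPpos against YFPneg cells with SGC0946, and 3424 for SGC0946 against SGC0649 in YFPpos cells. The highest of the other splits gave 0 genes by the edgeR test in each, with up to 70, 822 and 930 genes at an unadjusted p under 0.05, and other tools were not run on the splits. Each of the other splits mixes libraries of both real groups, so the difference between these groups enters the spread and leaves few calls, whatever its cause. With 10 splits a share under 0.05 cannot be reached either, and no conclusion is drawn from the splits.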

How the results depend on the processing

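All alternatives were planned except the one without the libraries that stood apart, chosen after seeing the data, and they left most results in place. Of 3584 checks on named genes 3417 kept direction and side of the threshold, 159 lost and 5 gained a call and 3 changed sign; of 454 on gene lists 429 kept both, 23 lost and 1 gained a call and 1 changed sign. The cause was not tested unless given.

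A fit to the compared groups alone has fewer samples behind the spread and takes it from those groups only. In it SGC0946 in YFPneg cells changed 199 genes in place of 1065 and the interaction 56 in place of 142. Between replicate libraries the Pearson r of log2 CPM was 0.9973 to 0.9974 in naive, 0.979 to 0.991 in YFPneg and 0.994 to 0.998 in YFPpos cells. Whether the number of samples or the unequal spread lowered the counts was not tested. The DESeq2 Wald test gave 300 for the interaction. Other alternatives kept each count of genes within 1.5 times. With 1 library left out, counts ranged from 1886 (without YFPpos SGC0649 replicate 3) to 3449 for SGC0946 in YFPpos cells, from 335 (without YFPneg SGC0649 replicate 2) to 1520 for SGC0946 in YFPneg cells and from 61 (without YFPneg SGC0649 replicate 1) to 241 for the interaction. Leaving out a YFPneg SGC0649 library leaves 1 in its group, which is assumed to vary like the others. Without both SGC0946 libraries that stood apart the counts were 6248 for the reporter with SGC0946, 3196 for SGC0946 in YFPpos cells, 1415 in YFPneg cells and 108 for the interaction. In the 5 pairs of YFPpos and YFPneg libraries with the same number and compound, the r of deviations was 0.0046 to 0.2769, above 0.1 in 3 pairs, and 3 of 5 YFPneg libraries were closest to their own number. It was above 0.1 in 9 of 15 pairs with the same number among cultured groups and 9 of 26 with naive cells included. For YFPneg and YFPpos libraries, the mean r with the same number was 0.1789 with SGC0649 and 0.1063 with SGC0946. With different numbers it was -0.0894 and -0.0536. Deviations cancel within a group, so these means are tied, and those of the YFPneg SGC0649 libraries mirror each other. Pairing is therefore not excluded. Since not every pair passed 0.1 and the labels name no shared culture, the reported fits have no block.

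Camera with an estimated correlation called 3, 6, 3, 4, 0, 1 and 0 lists in the 7 comparisons, in their order above, in place of 11, 12, 10, 11, 9, 11 and 7. At an unadjusted p under 0.05 it had 3 lists for SGC0946 in YFPpos cells and 4 for the interaction, where fry called 15 and 5. Lists called for SGC0946 in YFPneg cells ranged from 7 (without YFPneg SGC0649 replicate 2) to 12 with 1 library left out.

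Signs changed for values near 0. The interferon list in YFPpos SGC0649 against naive cells pointed up with no filter (adjusted p 0.824). With 1 library left out the interaction of Dot1l ranged from -0.272 to 0.0192, Gata3 with SGC0946 in YFPneg cells from -0.142 to 0.345 and Ifng with SGC0946 in YFPpos cells from -0.311 to 0.009997. At this depth, genes with a few counts per group have wide intervals, as for Ifng in naive cells.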

Other observations

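The Pearson test in the last paragraph was written before its result was seen, whereas its rank coefficients and shares were not part of the written test, and the gene families below were chosen after their values were seen. Of 15 tested chemokine receptor genes 8 rose with SGC0946 in YFPpos cells and 4 fell. Those that rose included Cxcr4 (log2 fold change 2.12, SE 0.16) and Ccr2 (2.11, SE 0.17), a receptor for chemokines of inflamed tissue. Cxcr3, a receptor typical of Th1 cells, had -1.38 (SE 0.28), Ccr8 -1.10 (SE 0.24), Ccr7 -0.69 (SE 0.06) and Ccr4 -0.49. The adjusted p of Ccr4, 0.011, became 0.081 without YFPpos SGC0649 replicate 3 and 0.055 without YFPpos SGC0946 replicate 2 (0.0033 to 0.081 over its alternatives). The metallothioneins Mt3 (2.98, SE 0.37), Mt2 (2.58, SE 0.42) and Mt1 (2.39, SE 0.37), which bind zinc and copper, all rose. These counts were the same with DESeq2 size factors.

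Guanylate-binding proteins, GTPases of cell-intrinsic defence, also rose with SGC0946 in YFPpos cells, 9 of 10 tested, with Gbp4 at 0.91 and Gbp3 at 0.72. Of 13 KLR genes, which encode receptors shared with NK cells, 8 rose, including Klrd1 (1.28, SE 0.30), and of 8 MHC class II genes 6 rose. In the marker lists fixed in advance, Klre1 (1.45) and Klri2 (1.04) rose of 5 NK cell markers, and Batf3 (1.23) and Flt3 (3.39) of 5 dendritic cell markers (camera adjusted p 0.38 and 0.35). Flt3 went from 0.0876 to 1.02 CPM of the library total, its log2 fold change was 5.11 without YFPpos SGC0649 replicate 1, and its adjusted p of 0.017 became 0.077 and 0.085 without YFPpos SGC0649 replicates 2 and 3 (0.0025 to 0.085 over its alternatives). Without a single one of these libraries or of the 3 YFPpos SGC0946 libraries the adjusted p of Klre1, 0.020, became 0.054 to 0.10 and that of Klri2, 0.036, became 0.078 to 0.17, with a lowest value over the alternatives of 0.0022 and 0.0046. The cytokine gene Il10 rose from 8.32 CPM ± 2.84 (SD, n = 3) to 26.0 ± 3.38 (n = 3), a log2 fold change of 1.64 (SE 0.26). The counts of these families, too, were the same with DESeq2 size factors.

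A hypothesis was that SGC0946 moves cells further along the change from naive to cultured cells. Across genes, the SGC0946 fold changes in YFPpos cells and those of YFPneg SGC0649 over naive cells had a Pearson r of 0.117 and a Spearman rho of 0.026, and the fold changes in YFPneg cells and those of YFPpos SGC0649 over naive cells 0.139 and -0.070. Of the genes called between cultured and naive cells, 48.8% and 41.94% had the same sign under SGC0946. Both Pearson coefficients passed the bound of 0.1 written beforehand. Outside that written test, the first rank coefficient was close to 0, the second was negative, and the shares lay below an even split, so the values leave the hypothesis undecided.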
